A study of Bos taurus
Mus musculus with 10 samples.

How the data were processed

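RNA was measured by poly(A) RNA sequencing in 10 wells that each held bovine embryonic stem cells growing on mouse embryonic fibroblast feeders. Libraries were made with a NEBNext Ultra kit, per the labels' protocols. The labels state that reads were mapped separately to the bovine genome ARS-UCD1.3 and to the mouse genome GRCm39. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 without giving their roles. How reads that align to both genomes were treated is not given in the sources used here.

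The authors deposited 1 table per species, with a normalised signal per gene and library. In the values, each library's entries were whole multiples of 1 step that differed between libraries, which is the pattern of a read count divided by a size factor. Dividing by that step gave whole reads for 100% of the positive values in every library, at a tolerance of 0.01 reads. No label or header records the scaling, so it is read from the deposited signal values alone. The recovered reads per library amounted to 48064953 to 64345738 for bovine genes and 17101894 to 35223039 for mouse genes. Counting error was not set against the spread between wells; relative to the count, it is largest for genes near the filter. The mouse table also held 2 columns without a sample label, which were not used. The size factors of the other columns may have been set with them.

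Genes carried NCBI gene IDs. Of 27590 bovine IDs, 24660 matched a RefSeq gene table of assembly ARS-UCD2.0, which gave the symbols. Because that assembly differs from the one the labels name, no coordinates are given. Of 31349 mouse IDs, 0 matched a name in the tables used here, and the files do not pair IDs with names, so mouse genes appear only as IDs. Tests that need mouse gene names were therefore not run: the mouse gene lists, the interaction between species, and the named Wnt and fibroblast genes of the mouse.

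The design written before the data were examined assumed raw counts and edgeR's quasi-likelihood test. Because the tables hold scaled values, the test used was limma (version 3.58.1, in R 4.3.3) with an intensity trend, on log2(value + 1), for genes with a value of at least 10 in at least 5 libraries. A fold change on this scale understates the change of low genes. Benjamini-Hochberg adjusted p-values under 0.05 were called. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads served as alternatives.

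The comparison was medium without IWR-1 against medium with it, 5 wells each. The fit planned as primary had the medium as its only term, and the fit with the stem cell line as a block was fixed beside it as an alternative. The line numbers pair the wells because both wells of a number came from the same cell line, per the labels. Deviations from the group means correlated within each line at 0.617 to 0.883 in the bovine table and 0.488 to 0.725 in the mouse table. The line took 85.9% of the sum of squares of log values in the bovine table and the medium 3.64%; in the mouse table the shares were 74.2% and 8.33%. The unblocked fit called 0 genes in either table, so the values given are those of the line-paired fit unless stated, and "rose" and "fell" refer to calls in it. The line-paired fit sets the mean change against its spread between lines, with a variance that limma moderates across genes. Its p-values and standard errors are thus not those of the 5 lines of a gene alone. Each line gave 1 well per medium, so that spread also holds differences between wells.

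Gene lists were fixed before the data were examined. There were 26 lists with at least 5 tested bovine genes. They were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated per list. The directional test of fry, which does not compare a list with other genes, was a further alternative. The mouse share of a well is its recovered mouse reads over all its recovered reads, tested with exact two-sided permutation tests.

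Named genes followed a rule fixed beforehand. It takes up to 10 genes per direction with the largest log2 fold change among called genes that moved the same way in all 5 lines, had a mean CPM of at least 1 and had a proper symbol, filled from the line-paired fit. It adds up to 4 members of each list with the smallest adjusted p, and always AXIN2, LEF1, SP5, NKD1, NOTUM, TBXT, POU5F1, SOX2 and NANOG. Of genes without names, 2 per direction are given for the mouse. Genes outside the rule are said to be so where they appear.

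Both fits were tested on simulated data, with 100 genes changed 1.5-fold and 100 changed 2-fold. The data had the real means of each line and a spread per gene estimated with the line as a block. Each gene was drawn on its own, with the same fold change in every line, a setting that favours the line-paired fit. Real genes vary together and real changes differ between lines, so the shares below do not carry over to the real calls. The changed genes were drawn only from genes with a mean well above the filter value of 10. Recovery of genes near the filter was therefore not simulated. In the bovine simulation, run on 18239 genes, the line-paired limma fit recovered 85% and 95% of them, with a share of false calls of 5.76%. The unblocked fit recovered 6% and 47%. In the mouse simulation, run on 15646 genes, the line-paired fit recovered 78% and 98%, with a share of false calls of 6.38%, and the unblocked fit 10% and 59%.

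The alternatives were other tools, scaling factors and pseudocounts, no filter on low values, the mouse share of the well as a covariate, a 2-fold minimum, robust variance shrinkage, and each library or line left out. Alternatives that restrict genes to those with a symbol in both tables could not be run without mouse names.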

Results

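The data compare cultures of bovine embryonic stem cells and their feeder cells with and without 1 day of withdrawal of IWR-1. IWR-1 is a tankyrase inhibitor that stabilises AXIN and so dampens Wnt/beta-catenin signalling, and it is a component of the medium in which these stem cells are kept. Lines 1, 2, 4, 8 and 11 had been derived from blastocysts of day 7.5. Each was grown on fibroblasts from mouse fetuses whose division had been stopped with mitomycin C. Each line was divided over 2 wells, of which 1 kept medium with 2.5 µM IWR-1 and the other received medium without it. The 10 wells gave 5 libraries per medium. In every library reads were counted separately on bovine genes, 48064953 to 64345738 reads, and on mouse genes, 17101894 to 35223039 reads.

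The share of assigned reads on mouse genes was compared between media; how reads that align to both genomes were treated is not given in the sources used here. The mouse share was 30.4% ± 7.57 (SD, n = 5) with IWR-1 and 26.8% ± 8.45 (SD, n = 5) without it. It was lower without IWR-1 in 5 of 5 lines, by a mean of -3.64 percentage points. The lines differed more than the media, so that the unpaired exact permutation test gave p = 0.452. The exact sign-flip test of the 5 within-line differences gave p = 0.0625, which is the smallest p that 5 pairs allow. Line 4 stood apart, with mouse shares of 42.3% and 41.4%, against 21.2% to 33.3% in the other lines.

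**Figure D1:**
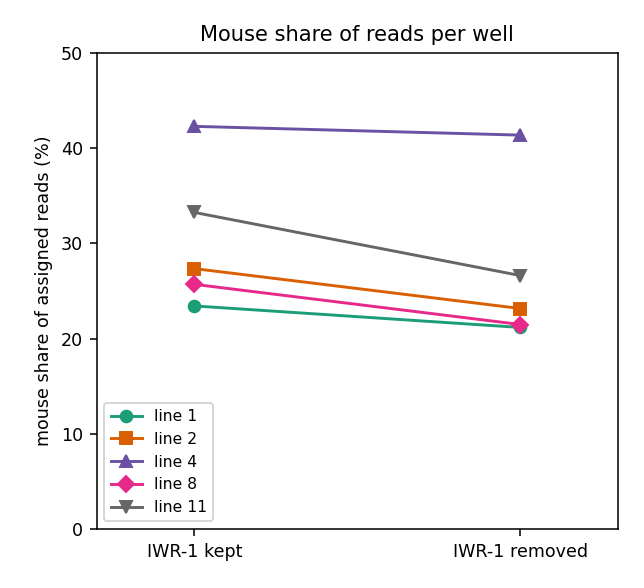
Mouse share of assigned reads (%) in each of the 10 wells, with a line joining the wells of each stem cell line. The share was lower without IWR-1 in 5 of 5 lines, and line 4 lay above 41% in both wells.

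Line 4 also differed from the other lines in its bovine transcripts, in both media. Genes of fibroblasts and mesenchyme were high in it; those named here were chosen after their values were seen. With IWR-1, the collagen genes COL1A2 and COL3A1 reached normalised read counts of 28291 and 27503 in line 4, against 134 to 372 and 4.05 to 484 in the other lines. The matricellular gene POSTN stood at 4097 against 0 to 14.6. AXIN2 stood at 3202 against 228 to 461 and LEF1 at 3038 against 119 to 326. The pluripotency gene SOX2 was lowest in line 4 in both media, at 13611 against 14750 to 22072 with IWR-1 and 13371 against 14958 to 19067 without it.

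The place of line 4 was then counted over whole lists, a tally chosen after these values were seen. Line 4 was the highest of the 5 lines in both media for 19.1% of all 18506 tested genes and the lowest in both for 18.4%. Of the 26 lists, the 6 with the largest share of members highest in line 4 were fibroblast and mesenchyme markers (18 of 22, lowest for 2), Wnt/beta-catenin target genes (18 of 23, lowest for 1, PROX1), extracellular matrix (24 of 34, lowest for 3), HOX genes (10 of 15, lowest for 0), primitive streak and mesendoderm (10 of 16, lowest for 2) and mesoderm (10 of 16, lowest for 1). The 4 with the largest share lowest in line 4 were glycolysis and hypoxia (16 of 27, highest for 1), trophectoderm (5 of 10, highest for 3), primed pluripotency (8 of 17, highest for 3) and core pluripotency (7 of 15, highest for 0). Genes within a list vary together, and line 4 is 1 line, so these counts were given no p.

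**Figure D2:**
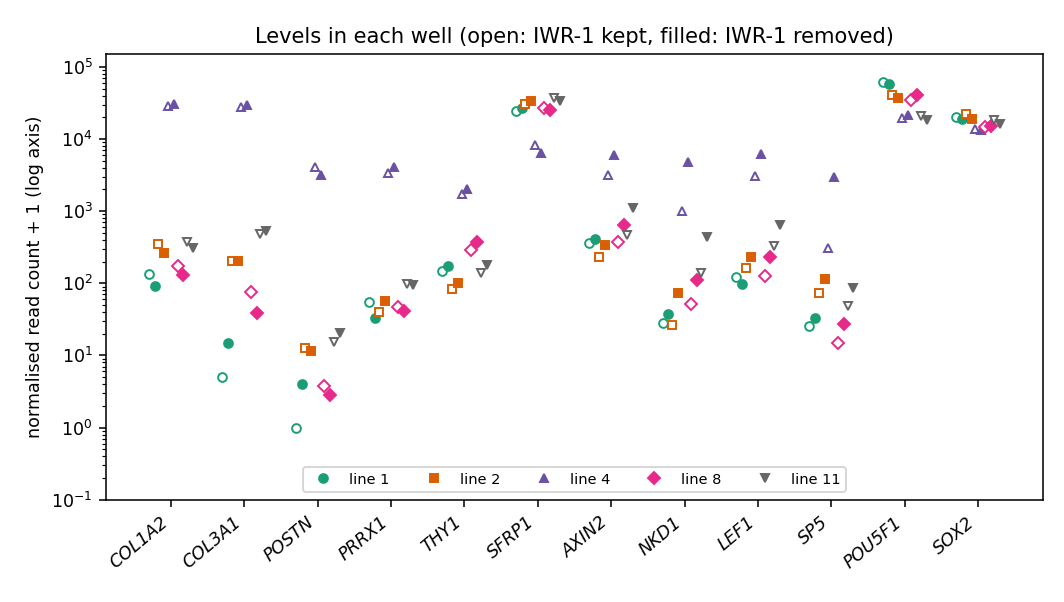
Normalised read count plus 1 (log axis) of 12 bovine genes in each well, with open symbols for medium with IWR-1 and filled symbols for medium without it; symbols and colours mark the 5 lines. Line 4 lies above the other lines for COL1A2, COL3A1, POSTN, PRRX1, THY1, AXIN2, NKD1, LEF1 and SP5, and below them for SFRP1.

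Among bovine genes, most of those called rose after IWR-1 withdrawal. With the line as a block, 164 genes rose and 12 fell among 18506 tested, and all 176 moved the same way in 5 of 5 lines. The paired test favours genes whose lines agree. Of all tested genes, 11.1% moved the same way in 5 of 5 lines, against 6.25% for signs drawn at random. Genes share the same wells and vary together, so this excess was given no p. The median log2 fold change was 0.59 for the genes that rose and -0.46 for those that fell. Changes of at least 2-fold were seen in 24 genes upward and 1 downward. Among genes with a mean CPM of at least 1, the largest rises were those of DMRTA1, a DM-domain transcription factor (log2 fold change 2.54 ± 0.45 SE, limma adjusted p = 0.0318), ANKRD1 (1.92 ± 0.31), MSX1 (1.83 ± 0.25), FAM83B (1.71 ± 0.22) and FAM20A, a pseudokinase of the secretory pathway (1.61 ± 0.17). The size for DMRTA1 comes from lines with few reads: with IWR-1 it stood at 0 to 23.2 normalised reads in lines 1, 2, 8 and 11, and in line 4 it was at 637 with IWR-1 and 649 without it (log2 change 0.03). USP43, a ubiquitin-specific protease, went from 111 ± 60.6 to 301 ± 124 normalised reads (SD, n = 5). SH3RF2, a RING-finger ubiquitin ligase, went from 299 ± 131 to 830 ± 373 (SD, n = 5), with a limma adjusted p of 0.000656. SYNE3 (1.42), NKD1 (1.39) and the natriuretic peptide clearance receptor NPR3 (1.37) completed the 10 largest. With 1 line left out, FAM20A, USP43, SH3RF2 and SYNE3 were called in each of the 5 fits. The calls ended for DMRTA1 without line 1, 2, 8 or 11 (log2 fold change 2.25 to 3.17 over the 5 fits), ANKRD1 without line 1 or 11 (1.60 to 2.15), MSX1 without line 11 (1.55 to 1.97), FAM83B without line 1 (1.52 to 1.93), NKD1 without line 4 or 11 (1.17 to 1.64) and NPR3 without line 1, 8 or 11 (1.21 to 1.63).

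Of the 12 genes that fell, 6 had a proper symbol and met the naming rule. NKX2-8, a homeobox gene, fell by 1.45 ± 0.27 on the log2 scale, from 189 ± 268 to 82.8 ± 111 normalised reads (SD, n = 5). Its largest falls were in lines with few reads, from 25.3 to 3.89 in line 11 and from 7.14 to 1.15 in line 4. The ephrin receptor EPHB1 (-0.59), the apelin receptor APLNR (-0.54), the opioid precursor PDYN (-0.45), the NAD synthesis enzyme NMNAT2 (-0.42) and the secreted matrix protein SMOC1 (-0.38) fell less. Limma adjusted p-values of these 6 lay between 0.0214 and 0.0471. With 1 line left out, EPHB1 (-0.65 to -0.48) and PDYN (-0.47 to -0.41) were called in 0 of 5 fits. The calls ended for NKX2-8 without line 1, 2, 4 or 11 (-1.63 to -1.21), SMOC1 without line 1, 4, 8 or 11 (-0.42 to -0.33), and APLNR (-0.59 to -0.46) and NMNAT2 (-0.44 to -0.41) without line 1, 4 or 11.

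These calls depend on comparing wells within lines. Without the block, limma called 0 genes, with 105 at an unadjusted p under 0.05 where 925 would be expected by chance; edgeR called 0 and DESeq2 called 2. With the block, 36 genes were called without line 1, 185 without line 2, 102 without line 4, 151 without line 8 and 31 without line 11, and 0 with the mouse share of the well as a covariate. The covariate fit kept the sign of all 176, with a median size of 0.47 against 0.56 on the log2 scale, and its standard errors were larger (median 0.19 against 0.09).

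Several Wnt/beta-catenin target genes rose. Of 23 tested members, 7 rose, 0 fell and 16 were not called, and 22 had a positive log2 fold change (median 0.52). Adjusted over the list alone, 15 rose and 1 fell. Those that rose included CCND1, encoding cyclin D1 (log2 fold change 1.15 ± 0.12 SE, limma adjusted p = 0.0027), the homeobox genes MSX1 (1.83 ± 0.25) and MSX2 (0.94 ± 0.13), and NKD1 (gene ID 618586), a feedback inhibitor of the pathway (1.39 ± 0.22). AXIN2 (gene ID 511619), which encodes a scaffold of the beta-catenin destruction complex and is itself induced by Wnt signalling, rose by 0.74 ± 0.13 (limma adjusted p = 0.0258), from 924 ± 1277 to 1685 ± 2400 normalised reads (SD, n = 5). The other 2 that rose, outside the naming rule, were TCF7 (0.61 ± 0.11) and the R-spondin receptor gene LGR5 (0.89 ± 0.17). LEF1 was not called over all genes, with a log2 fold change of 0.61 ± 0.17, positive in 4 of 5 lines (limma adjusted p = 0.181). SP5 had 1.18 ± 0.35 (adjusted p = 0.21), or 0.67 without line 4, and NOTUM 0.52 ± 0.23 (adjusted p = 0.477). The mesoderm gene TBXT was below the filter. It had 64 recovered reads with IWR-1 and 148 without it in line 4, against 0 with IWR-1 and 1 to 3 without it in the other lines.

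The Wnt target list ranked above other genes (camera adjusted p = 1.82e-17 with the line as a block), a call that was lost with an estimated correlation (adjusted p = 0.085). The call for AXIN2 was lost without line 4, 8 or 11 (log2 fold change 0.61 to 0.87 over the 5 fits that leave out 1 line), and that for MSX2 without line 11 (0.82 to 1.02), whereas CCND1 was called in each of those 5 fits.

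On the 2 fixed lists of Wnt pathway components, which leave out AXIN2, NKD1 and LGR5, no gene was called. Among 34 Wnt ligands, receptors and secreted modulators 0 rose and 0 fell. FZD4 was at 0.50 ± 0.12, FZD10 at 0.24 ± 0.09 and WNT4 at -0.41 ± 0.16 (-0.55 to -0.26 with 1 line left out). RSPO4 was at 1.53 ± 0.45, near the filter at 4.41 ± 3.71 and 12.3 ± 4.17 normalised reads with and without IWR-1 (SD, n = 5). Of these 34 genes, 23 had a positive log2 fold change. Their list ranked slightly high (camera adjusted p = 0.0252 with the block, adjusted p = 0.398 with an estimated correlation), and lost its call without line 2, 8 or 11 (adjusted p = 0.0738, 0.199 and 0.129). Among 21 genes of the destruction complex and the tankyrases 0 were called, with AXIN1 at 0.12 ± 0.05 and the tankyrase gene TNKS, whose product IWR-1 inhibits, at -0.16 ± 0.09 on the log2 scale, or -0.06 without line 8 (camera adjusted p = 0.25 for the list, and 0.0226, for a low rank, without line 2).

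Targets of YAP and TAZ, the co-activators of the Hippo pathway, were in part higher without IWR-1, as were contractile genes. Of 25 tested YAP/TAZ targets 7 rose, 0 fell and 18 were not called; 24 had a positive log2 fold change (median 0.22), and 13 rose when adjusted over the list alone. CCN1 (gene ID 508941), a secreted matricellular protein, went from 3031 ± 731 to 6129 ± 920 normalised reads (SD, n = 5; log2 fold change 1.04 ± 0.09 SE, limma adjusted p = 0.00108). CCN2 rose by 0.78 ± 0.06 (limma adjusted p = 0.000656), and AMOTL2 (0.54 ± 0.06) and AJUBA (0.52 ± 0.05), a pair of regulators of the Hippo pathway, rose in every line. ANKRD1 (1.92 ± 0.31) and, outside the naming rule, GADD45A (0.79 ± 0.11) and WWC1 (0.41 ± 0.08) also rose. CCN1, CCN2, AMOTL2 and AJUBA were called in each of the 5 fits that leave out 1 line. The list ranked above other genes (camera adjusted p = 4.17e-18 with the block; adjusted p = 0.085 with an estimated correlation).

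The smooth muscle actin gene ACTA2 (0.87 ± 0.09 SE) and TAGLN, which encodes an actin-binding protein (0.90 ± 0.08), were the 2 of 22 tested fibroblast and mesenchyme markers that rose. None fell, and 20 were not called. Adjusted over the list alone, 8 rose and 1 fell. PDGFRB was at 0.56 ± 0.12 and LOX at 0.39 ± 0.08. The collagen genes of the list, outside the naming rule, went both ways. COL1A1 was at 0.36 ± 0.08 (limma adjusted p = 0.0711 over all genes and 0.00422 over the list alone). COL3A1 was at 0.17 ± 0.26, COL6A3 at -0.16 ± 0.20 and COL1A2 at -0.30 ± 0.10. This list, which marks the cell type of the feeders, ranked high (camera adjusted p = 1.26e-05 with the block; adjusted p = 0.085 with an estimated correlation). The mouse share of reads was lower without IWR-1 in 5 of 5 lines.

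**Figure D3:**
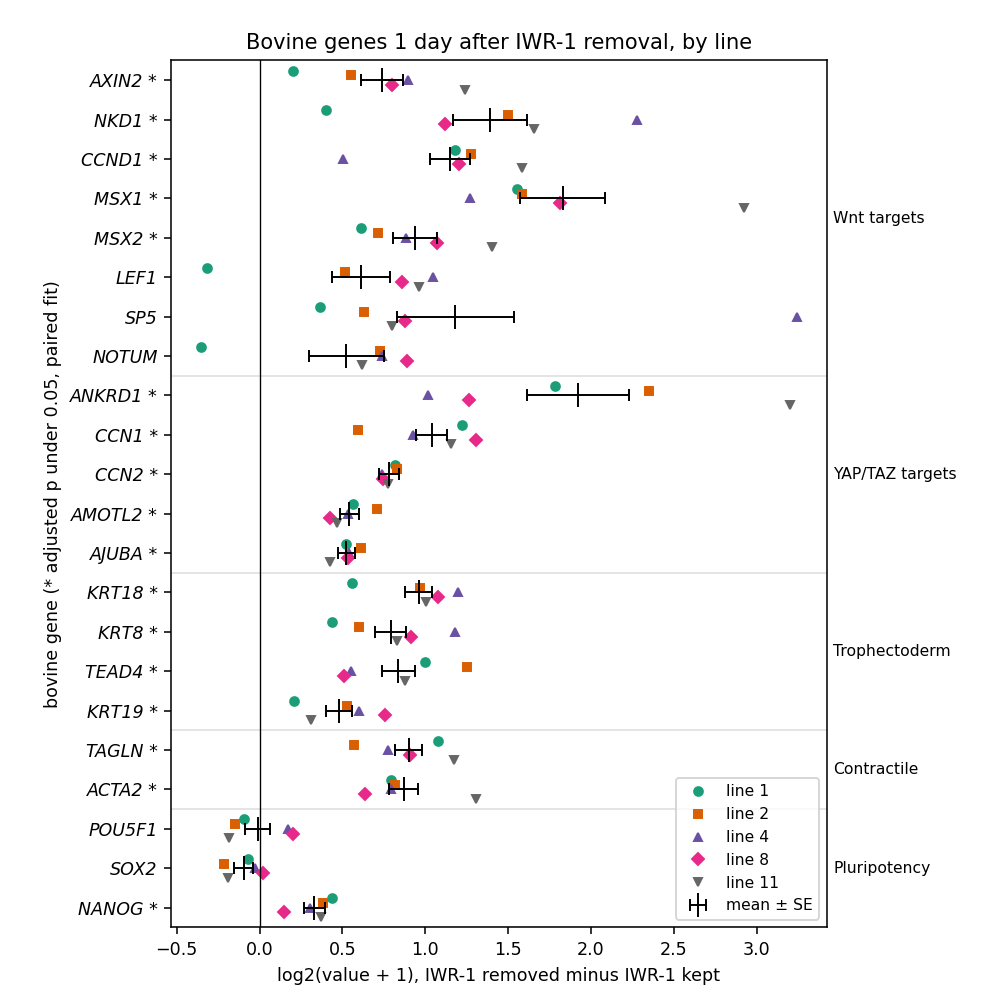
Log2 change in value + 1 (IWR-1 removed minus kept) of 22 bovine genes in each of the 5 lines, with the mean and its standard error from the line-paired limma fit. CCN1, CCN2, AMOTL2 and AJUBA lie above 0 in all 5 lines, NKD1 and SP5 were highest in line 4, and POU5F1 and SOX2 lie around 0.

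Some keratin genes on the trophectoderm list rose. The fixed list holds 22 genes, of which 19 matched a name and 10 were tested. The lineage genes CDX2, GATA2, GATA3 and ELF5 were among those not tested. Of 10 tested members 4 rose, 0 fell and 6 were not called; 9 had a positive log2 fold change, and 5 rose when adjusted over the list alone. KRT18 went from 4771 ± 2685 to 9296 ± 5797 normalised reads (SD, n = 5; log2 fold change 0.96 ± 0.08 SE, limma adjusted p = 0.00108). KRT8 rose by 0.79 ± 0.09, KRT19 by 0.48 ± 0.08 and TEAD4, a partner factor of YAP, by 0.84 ± 0.10. These keratins are general genes of simple epithelia. The 6 members not called were DAB2 (0.46 ± 0.11; adjusted p = 0.118 over all genes and 0.00469 over the list alone), PTGS2 (0.25 ± 0.31), KRT7 (0.11 ± 0.15), TFAP2C (0.07 ± 0.41), DSC2 (0.05 ± 0.08) and TFAP2A (-0.70 ± 0.48). The list ranked high (camera adjusted p = 2.72e-07 with the block; adjusted p = 0.085 with an estimated correlation). TEAD4 lost its call without line 1 (limma adjusted p = 0.0506) and KRT19 without line 1, 4 or 11 (log2 fold change 0.41 to 0.55 over the 5 fits).

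Few core pluripotency genes passed the test. Of 15 tested members 1 rose and 0 fell, or 2 and 2 when adjusted over the list alone. NANOG went from 1550 ± 263 to 1970 ± 454 normalised reads (SD, n = 5; log2 fold change 0.33 ± 0.06 SE, limma adjusted p = 0.0411), a call lost without line 1, 2, 4 or 11 (log2 fold change 0.30 to 0.37 over the 5 fits). POU5F1 was at -0.01 ± 0.08 and SOX2 at -0.10 ± 0.06, neither called. DNMT3B was at -0.27 ± 0.07 and FOXD3 at -0.44 ± 0.10. Among 12 naive and 17 primed pluripotency genes none was called over all genes; adjusted over the list alone, 2 naive genes rose, and 1 primed gene rose and 1 fell, with SUSD2 at 0.30 ± 0.07 and POU3F1 at -0.37 ± 0.08. Camera with the block called none of these 3 lists (adjusted p = 0.904, 0.873 and 0.911).

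Single genes of several lineages moved. On the neuroectoderm and neural crest list the transcription factor gene PAX3 was the 1 of 14 members that rose (1.32 ± 0.21 SE), with 3 up and 3 down when adjusted over the list alone. On the mesoderm list BMP4 rose (0.72 ± 0.10) and APLNR fell by 0.54 ± 0.09, with 14 of 16 members not called; adjusted over the list alone, 2 rose and 1 fell. On the endoderm list PRDM1, a transcriptional repressor, was the 1 of 11 members that rose (0.59 ± 0.10), or 3 adjusted over the list alone, and the list ranked high (camera adjusted p = 0.00441 with the block, 0.295 without it; adjusted p = 0.137 with an estimated correlation). None of 16 primitive streak genes was called over all genes, and 3 rose when adjusted over the list alone, with EOMES at 0.45 ± 0.11 and NKX1-2 at 0.94 ± 0.23. Of 11 BMP targets the BMP antagonist GREM1 (1.28 ± 0.12, limma adjusted p = 0.00128) and ATOH8 (0.98 ± 0.16) rose, or 3 genes adjusted over the list alone. The list ranked high (camera adjusted p = 0.0149 with the block, 0.108 without it; adjusted p = 0.398 with an estimated correlation), a call lost without line 8 (adjusted p = 0.289). PAX3 lost its call without line 1, 8 or 11 (log2 fold change 1.15 to 1.61 over the 5 fits that leave out 1 line), ATOH8 without line 1, 4, 8 or 11 (0.93 to 1.09), PRDM1 without line 1, 4 or 11 (0.54 to 0.64) and BMP4 without line 11 (0.63 to 0.79). Camera with the block did not call the neuroectoderm, mesoderm or primitive streak lists (adjusted p = 0.489, 0.386 and 0.911), but the neuroectoderm list ranked high without line 4 (adjusted p = 0.00521).

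Among metabolic and stress lists, PSAT1, an enzyme of serine synthesis (0.60 ± 0.10 SE), and the amino acid transporter gene SLC7A5 (0.36 ± 0.07) rose, the 2 of 26 members called on the list of endoplasmic reticulum stress and the amino acid response. Adjusted over the list alone, 9 rose and 1 fell. The list ranked high (camera adjusted p = 2.47e-08 with the block; adjusted p = 0.137 with an estimated correlation). On the list of glycolysis and hypoxia the angiogenic factor gene VEGFA rose (0.63 ± 0.09), 1 of 27, or 3 adjusted over the list alone. That list also ranked high (camera adjusted p = 0.0014 with the block, 0.108 without it; adjusted p = 0.401 with an estimated correlation), a call lost without line 2 (adjusted p = 0.0762). Of 22 genes of cholesterol synthesis 0 were called, 1 rose when adjusted over the list alone, and 20 had a positive log2 fold change, with MVD at 0.28 ± 0.06 and DHCR7 at 0.19 ± 0.06 (camera adjusted p = 1.34e-05; adjusted p = 0.233 with an estimated correlation). The chemokine gene CXCL12 (0.49 ± 0.07) was the 1 of 13 called on the NF-kB list, over all genes and over the list alone (camera adjusted p = 0.00441 with the block, 0.0841 without it; adjusted p = 0.322 with an estimated correlation), and the list lost its call without line 8 (adjusted p = 0.0623). Of 34 extracellular matrix genes, TIMP3 (0.51 ± 0.07), LOXL2 (0.42 ± 0.07) and the protease gene MMP3 (1.99 ± 0.38), which was near the filter at 5.63 ± 5.51 and 21.4 ± 12.6 normalised reads (SD, n = 5), rose (camera adjusted p = 0.000134; adjusted p = 0.398 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell. With 1 line left out, MMP3 was called in 0 of the 4 fits in which it passed the filter (log2 fold change up to 2.05). The calls ended for VEGFA (0.55 to 0.72) and CXCL12 (0.45 to 0.53) without line 1 or 11, PSAT1 without line 1, 8 or 11 (0.51 to 0.71), SLC7A5 without line 1, 4, 8 or 11 (0.28 to 0.39), and TIMP3 (0.48 to 0.58) and LOXL2 (0.37 to 0.48) without line 1, 4 or 11.

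No member was called on the lists of cell cycle and mitosis, p53 targets, interferon response, TGF-beta and nodal targets, FGF/ERK feedback, epithelial-mesenchymal transition or HOX genes, and camera with the block called none of these lists. Adjusted over the list alone, 1 FGF/ERK gene rose and 2 fell, and 1 p53 target rose. MCM4 was at 0.12 ± 0.06, PHLDA3 at 0.32 ± 0.07, IRF1 at 0.29 ± 0.14 (0.18 to 0.35 with 1 line left out), SMAD7 at 0.21 ± 0.06, SPRY2 at -0.21 ± 0.06 and ESRP1 at -0.29 ± 0.10 (-0.34 to -0.16). The HOX list ranked low without the block (camera adjusted p = 0.025) and was not called with it (adjusted p = 0.112), except without line 4, where it ranked low (adjusted p = 0.00625). The FGF/ERK list ranked low with the block without line 2 (adjusted p = 0.0309). Over all 26 lists, camera with the block called 12, all upward; without the block it called 8 upward and 1 downward. With an estimated correlation it called 0 in either fit.

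**Figure D4:**
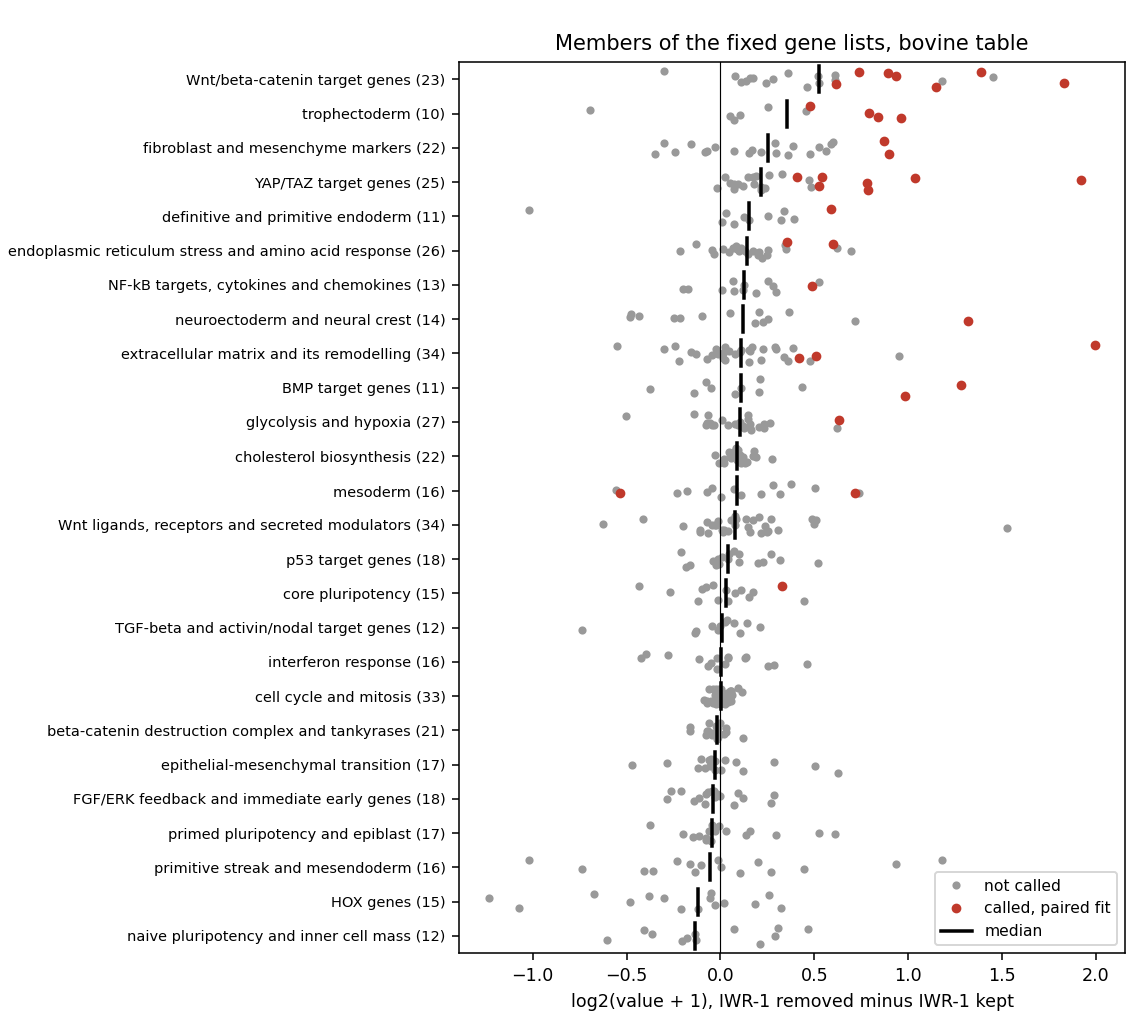
Log2 change in value + 1 (IWR-1 removed minus kept) of the tested members of the 26 gene lists, with the number of tested members in brackets. Red points are genes called in the line-paired limma fit, grey points are not called, and black bars are list medians. The Wnt target list has the highest median, 0.52.

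Among mouse genes, about as many rose as fell. With the line as a block, 340 mouse genes rose and 325 fell among 15871 tested, and 643 of these 665 moved the same way in 5 of 5 lines. Of all tested mouse genes, 15.7% did so, against 6.25% for signs drawn at random, an excess again given no p because genes vary together. The median log2 fold change was 0.58 for genes that rose and -0.49 for those that fell, and 36 genes rose and 36 fell by at least 2-fold. The files do not pair the mouse gene IDs with names. The gene with ID 27062 went from 77.9 ± 91.2 to 274 ± 279 normalised reads (SD, n = 5; log2 fold change 1.85 ± 0.15 SE, limma adjusted p = 0.000118), and ID 243958 from 18.0 ± 11.7 to 59.0 ± 40.3 (1.70 ± 0.24). ID 72948 fell from 70.1 ± 13.2 to 18.1 ± 7.88 normalised reads (-1.98 ± 0.29, limma adjusted p = 0.00274), and ID 20310 from 279 ± 360 to 91.3 ± 147 (-1.94 ± 0.30).

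Without the block limma called 0 mouse genes, with 584 at an unadjusted p under 0.05 where 794 would be expected by chance; edgeR called 0 and DESeq2 called 15. With the block the count was 319 without line 1, 772 without line 2, 283 without line 4, 935 without line 8 and 270 without line 11, and 0 with the mouse share of the well as a covariate. With that covariate all 665 kept their sign, at a median size of 0.51 against 0.54 and a median standard error of 0.22 against 0.10. Whether bovine and mouse genes responded differently was not tested, because mouse genes could not be matched to bovine ones. Bovine reads outnumbered mouse reads in every well, and the mouse share was lower without IWR-1 in 5 of 5 lines. Whether bovine reads counted on mouse genes contribute to the mouse calls was not tested.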

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

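The tests of the excess in line 4 and of the share of the list raised there were chosen after the result was seen. Among 248 groups of 5 wells examined for 1 well far from the others (121 genes taken by the naming rule, on the log2 scale, and the read totals and mouse share), 28 had such a well, or 11.3%, where chance gives about 5%. Of these wells 21 belonged to line 4, 6 to line 1 and 1 to line 2.

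In line 4 with IWR-1 the outlying normalised read counts were NPR3 at 644 (others 20.4 to 38.9), AXIN2 at 3202 (228 to 461), CCND1 at 3814 (501 to 772), CCN2 at 6038 (451 to 558), TGFBI at 7365 (3143 to 3777), ID2 at 5864 (1345 to 1928), TWIST1 at 731 (18.5 to 26.3), GBX2 at 5861 (204 to 298), NKX1-2 at 5683 (31.5 to 101) and COL4A1 at 16351 (5236 to 6259). In line 4 without IWR-1 they were FZD10 at 6662 (272 to 633), CCN2 at 10063 (757 to 962), TGFBI at 7570.2 (2668 to 3453), ISG15 at 63.5 (9.98 to 16.5), TWIST1 at 989 (24.5 to 39.4), SNAI2 at 659 (33.4 to 43.8) and GBX2 at 5919 (118 to 226). The read totals of line 4 stood apart too. Its bovine reads were 48064953 with IWR-1 and 49418754 without it, the lowest of each medium, and without IWR-1 its mouse reads were 34871196 and its mouse share was 41.4%, the highest of that medium.

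In line 1, EPHB1 was low at 71.9 with IWR-1 (others 430 to 799) and 56.2 without it (318 to 454). The stress genes TRIB3 and ATF3 were high in line 1, TRIB3 at 2073 (71.3 to 140) and 3265, and ATF3 at 1000.2 (186 to 278) and 1672 (271 to 449), with and without IWR-1. In line 2 without IWR-1, MCM4 was at 28681 (22619 to 23821).

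Fibroblast and mesenchyme genes were high in both wells of line 4. With feeders alike in all lines, mouse reads counted on bovine genes would raise line 4 by at most its excess of mouse reads. That excess, per bovine read, was 1.10 on the log2 scale. Over the 24 genes of the fixed list, the median excess of line 4 beyond that was 1.33, with a lower bootstrap bound of 0.44. This is more than mouse reads alone would add if the feeders were alike, which was not tested. The bootstrap resampled genes that vary together, so its bound does not measure the uncertainty about line 4, which is 1 line. A candidate explanation is a share of fibroblast-like cells of bovine origin in this line: 18 of the 24 genes, or 75%, were at least 2-fold above the mean of the other lines in both wells, short of the share set as the bound, and SFRP1 was lower, at 8384 against 24662 to 37502 with IWR-1. What cells carry these transcripts stays open, since stem cells that differentiate also express several of these genes.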

How the results depend on the processing

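The line-paired fit as a result of its own, its alternatives, edgeR with TMM factors, TMM-scaled limma, the pseudocounts, TMM-scaled lists, the block with an estimated correlation and the loss of both wells of line 4 were chosen after seeing the data; the others were planned. The cause was not tested where none is named. The replicate block raised the calls from 0 to 176 bovine and 665 mouse genes, and no replicate block gives 0 in each. Without the block, DESeq2 called 2 bovine and 15 mouse genes, the mouse share as a covariate gave 2 mouse genes, and the loss of both wells of line 4 gave 1; with single libraries left out, mouse calls ranged from 0 to 1, and bovine calls stayed at 0. With the block, DESeq2 called 422 bovine genes, 175 of the 176 among them. Without a filter on low values, which tests more genes, 53 bovine and 329 mouse genes were called, 53 and 327 of them shared with the reported calls. The mouse share as a covariate beside the block left 0 in both tables, and a minimum of 2-fold left 25 and 72. With 1 line left out, and so fewer wells, paired calls ranged from 31 to 185 in the bovine and from 270 to 935 in the mouse table. Of 42 named bovine genes called in the paired fit, 14 were called without any 1 line, and 42 kept their sign.

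Of 9 bovine lists called by camera without the block, 0 were called with the correlation estimated per list, 0 by fry and 0 with the replicate block and an estimated correlation; with single libraries left out the count ranged from 5 to 10. Of 12 lists called with the block, 0 held with an estimated correlation, and fry, a test against no change, called 4 (Wnt targets, YAP/TAZ targets, trophectoderm, fibroblast markers); with 1 line left out 9 to 14 were called. Without the line 4 library of the medium lacking IWR-1, the unblocked calls of the extracellular matrix and fibroblast lists ended and their direction turned (signed adjusted p, negative for a low rank, of -0.364 and -0.441). Over the single libraries left out, these signed values ranged from -0.364 to 0.859 and from -0.441 to 0.859. The difference in mouse share of assigned counts was negative and not called under every alternative run, from -7.29 points without the line 4 library lacking IWR-1 to -0.673 without the one kept in it, and -4.32 without both. The planned settings that need mouse gene names were not run. The effect of depth on the calls was not tested; counting error is largest near the filter, where MMP3 lies.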

Other observations

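The tests of the contractile list, of the reads added in line 4, of the other fibroblast markers and of other groupings of the wells were chosen after the result was seen. Of the bovine genes that rose, 131 of 164 lie outside the 26 lists tested in the bovine table. Those lists cover only a small part of the 18506 tested genes, so most genes lie outside them in any case. Some of the 131, such as LMOD1 and SPP1, are on lists fixed for the mouse table. The following were chosen after their values were seen. Of other actin genes, the skeletal form ACTA1 rose by 0.65 and the cardiac form ACTC1 by 0.77 on the log2 scale. ACTG2, a further actin gene, was at 0.31 and not called (limma adjusted p = 0.155). THBS1 (0.77), encoding thrombospondin, CAVIN1 (0.66), a component of caveolae, and the gap junction gene GJA1 (0.79) also rose. So did ANXA2 (0.76) and PIEZO1 (0.47), a mechanically gated channel. WLS, which encodes the carrier that Wnt ligands need for secretion, rose by 1.32, and SPP1 by 1.27. The lipid enzyme gene MOGAT1 went from 2462 to 5771 mean normalised reads, a log2 fold change of 1.16.

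The list of contractile genes had been fixed for the mouse table and was tested in the bovine table after ACTA2 and TAGLN were seen to rise. It was run first with all 14 tested members and then, after that result was seen, without those on the fibroblast list. In the second form 5 of its 10 genes rose (LMOD1, TPM1, CNN1, MYL9 and CALD1), with a median log2 fold change of 0.49. The list ranked above other genes with the line as a block (camera p = 6.12e-17; p = 0.000945 with an estimated correlation); fry, which sets a list against no change and not against other genes, gave p = 6.14e-05. The hypothesis is that withdrawal may raise contractile genes in the bovine cells as a group.

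Several explanations bear on the rise of YAP/TAZ targets and contractile genes. A larger share of fibroblast-like cells among the bovine cells would raise the other fibroblast markers alike. The median log2 fold change of the 18 other markers was 0.16 (quartiles -0.08 to 0.38), against a mean of 0.88 for ACTA2 and TAGLN. Those 2 were the only called members of the list, so the others were bound to lie lower. The median of the YAP/TAZ list, 0.22, lies within those quartiles, and that of the 10 contractile genes, 0.49, lies above them. The comparison therefore does not decide on this explanation. Reads of the mouse feeders counted on bovine genes should add more in line 4, which had 2.30 times the mouse reads per bovine read of lines 1, 2 and 8. Over the 14 called genes the median ratio of reads added in line 4 to those added in the other 3 lines was 1.56 with a bootstrap interval of 1.03 to 4.02, which holds both 2.30 and values well below it, so mouse reads cannot be told apart from a bovine response by this test. In line 1 with IWR-1, COL3A1 had 4 and POSTN 0 recovered reads but COL1A1 had 6742, so carry-over, if any, may differ between genes. A response of the stem cells to the medium stays open.

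The mouse share of the well as a covariate ended all calls of the paired fit. If the lower mouse share, and not the removal, were the whole cause, fold changes should shrink below 0.5 of their size. In the bovine table the called genes kept a median of 0.827 of their log2 fold change (quartiles 0.61 to 1.06): the median size went from 0.56 to 0.47, and the median standard error from 0.09 to 0.19. In the mouse table the ratio was 0.994 (quartiles 0.77 to 1.21), with sizes of 0.54 and 0.51 and standard errors of 0.10 and 0.22. With the covariate the standard errors thus grew and the median sizes fell, the latter more in the bovine table. The share and the medium go together within lines (squared correlation 0.779). The bound of 0.5 was fixed by choice. Every gene was fitted with the same shares, and the genes were those called without the covariate. The ratio therefore cannot tell whether the mouse share is the whole cause, a part of it or none.

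The wells were also grouped in other ways. Without the block, the real grouping called 0 bovine and 0 mouse genes. That 100 of 100 groupings, the real one included, gave as many or more was then fixed in advance, and says nothing about chance. The highest counts among them, 1625 bovine and 945 mouse genes, point to a structure of the wells. For the lists, 33 of 100 groupings gave at least the 9 called, up to 16, so chance cannot be excluded for that count. With the block, 16 groupings part all 5 pairs, too few for a share under 0.05. Of these 1, the real one, reached 176 bovine genes, 1 reached 665 mouse genes and 1 reached 12 lists; the highest of the others was 0 bovine genes, 0 mouse genes and 9 lists.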
